A study of Schistosoma mansoni and Schistosoma japonicum and Schistosoma haematobium with 60 samples.

How the data were processed

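Small RNA libraries from 20 specimens of S. mansoni, S. japonicum and S. haematobium were analysed, each with 1 untreated library and libraries treated for 5 and 10 min with duplex-specific nuclease, 60 libraries in all. Per the labels, total RNA was extracted with TRIzol and made into cDNA libraries by adapter ligation and gel selection, and the untreated and nuclease-treated libraries list different 3′ adapters. Sex was labelled for adults only.

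The deposited files are 3 tables of mapped reads, 1 per species, with 8323055 lines for S. mansoni, 3852464 for S. japonicum and 2228957 for S. haematobium. Per the file headers, each line gives a read name, length, sequence and mapped position. The count of identical reads is the number at the end of the deposited read name, a raw whole number, and the name starts with the code of the library. The remaining deposited columns hold other values, namely lengths, positions, strands and mismatches. Reads were analysed with miRDeep2 per the series text; its version, the mapper settings and the genome builds are not given in the sources used here. Every line was checked: reads were at least 18 nt long, had at most 5 positions and 2 mismatches, and 0 lines had a mismatch in nt 1 to 18. All library codes matched a label.

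A read of 18 to 26 nt was given to 1 of 63 listed sequences when its nt 2 to 8 were identical and nt 1 and 9 to 18 held at most 2 mismatches; ties were dropped. The list held 37 schistosome miRNAs written from known families, 10 mammalian and 6 mollusc miRNAs, and 10 synthetic spike-in sequences. Of the schistosome miRNAs, 3 had no read. A read was counted once per name, as often as its name states. Positions are 1-based, on the scaffolds named in the deposited tables.

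The design set down before the data were examined named a quasi-likelihood test on counts. The tables hold no plain count column, and the test used was limma with voom weights (limma 3.58.1, R 4.3.3) on the numbers in the read names, which replaces the planned one; the planned count model was not run, although whole numbers would allow it. A miRNA was tested with at least 10 reads in at least 2 libraries of the fit. Library sizes were listed reads scaled by trimmed means of M values (trim of 30% on M and 5% on A), with a prior count of 0.5, and Benjamini-Hochberg adjusted p under 0.05 was called. Log2 fold changes and folds of the fits are thus relative to the listed total after this scaling, and can differ from ratios of RPM. Those of miRNAs at low counts depend on the prior. Where a miRNA had 0 reads in a species, the floor is 3 reads of the total.

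Stages and species were compared in 1 fit of the 18 untreated libraries of adults, eggs, cercariae and miracidia, with species and stage as terms. It had 12 residual degrees of freedom. Sexes were compared over 4 female and 3 male libraries with species as a term, and the same fit was run on 27155 tags (the first 18 nt of reads of 20 to 24 nt) outside the list. The nuclease was tested over all 60 libraries with the specimen as a block. The labels tie the 3 libraries to 1 specimen; deviations from the group means over 28 miRNAs correlated between the untreated and 10 min library of a specimen with a median r of 0.961 (lowest 0.587, 20 pairs), against -0.099 between different specimens (380 pairs). Shares were compared by permutation of signs within specimens (100000 resamples, two-sided). In the sporocyst and schistosomula, shares have Wilson 95% intervals. Adjusted p-values for stages, species and sexes rest on the spread between these specimens, estimated in part over all miRNAs together. Those for the nuclease rest on the spread of libraries within specimens. Comparisons against adults share the adult libraries.

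The text names every called miRNA with at least 100 RPM in a group, up to 25 per comparison, and in each comparison also let-7, bantam, miR-71a, miR-125b, miR-1, miR-31 and miR-36. Of the unlisted tags it names the 5 with the lowest adjusted p in each direction with at least 100 reads in a library. Other miRNAs are named where they belong to a list result.

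The fits were tested on simulated data, 50 tables with 8 changed miRNAs of 33 each. For eggs against adults the test recovered 3.50%, 12.8% and 83.3% of changes of 2-fold, 4-fold and 16-fold, and called up to 1.52% of unchanged miRNAs. For females against males it recovered 3.31%, 25.5% and 88.2%, and called up to 2.00%. For the nuclease it recovered 86.5%, 97.0% and 97.8%, but called 7.12%, 17.3% and 24.7% of unchanged miRNAs. The simulated libraries had independent noise, so they do not cover the likeness of the libraries of a specimen. The tag fit was tested on 1 simulated table of 12390 tags with 200 changed by 16-fold, and recovered 0% of them.

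Between specimens of the same group the spread was far above counting error, with a chi-square over degrees of freedom of 1611 for the S. mansoni eggs and 3904 for the S. mansoni females. Alternatives tried were another library size and scaling, other read lengths, exact matching, no filter, the unweighted limma trend fit, nuclease-treated or summed libraries, the pool code as a term, no block, shallow libraries left out (under 20000 listed reads, or under 3000 for the nuclease), miRNAs under 100 RPM in a species set missing there, and each library or specimen left out. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 did the counting, permutations and figures. Mouse liver and human serum samples were not analysed here, and the table of gene symbols given with the data was not used here, since it does not list these miRNAs.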

Results

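Small RNA was sequenced from 20 specimens of parasitic blood flukes, of which 11 were Schistosoma mansoni, 5 Schistosoma japonicum and 4 Schistosoma haematobium. Each specimen gave 3 libraries, 1 untreated and 2 made after 5 or 10 min of duplex-specific nuclease (DSN), an enzyme that cuts double-stranded DNA and is used to thin out abundant cDNA. The 20 untreated libraries held 10 adults (4 female, 3 male, 2 of mixed sex and 1 of unspecified sex), 3 eggs, 3 cercariae, 2 miracidia, 1 sporocyst and 1 schistosomula. Most combinations of species, stage and sex had 1 specimen, and the 3 libraries of a specimen are repeats of 1 RNA preparation. The labels give a strain for part of the specimens. These are NMRI or PR1 in S. mansoni, Chinese or Philippine in S. japonicum and Egyptian in S. haematobium. Strain was not a term in any fit. The 60 libraries held 39871219 mapped reads, of which 11046422 matched a listed schistosome miRNA. Untreated libraries had 14029 to 6061317 mapped reads (median 470913.5) and 3653 to 2207511 listed reads (median 196390.5). The lowest totals of listed reads were 3653 in the S. mansoni mixed adult, 15816 in the S. japonicum female and 17259 in the S. mansoni miracidia. Levels are RPM, with the listed miRNA reads of a library as its total, given as mean ± SD over untreated libraries unless stated. Reads were amplified without molecular identifiers, so intervals and floors cover counting error only. The names of miRNAs rest on sequence matches to the list.

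Mammalian host miRNAs such as miR-122 and miR-451a, and families of the snail hosts such as miR-184 and miR-317, were looked for in the same libraries. The mammalian list of 10 gave 32 reads and the mollusc list of 6 gave 9 reads among all 39871219 mapped reads. The deposited tables hold reads that map to a schistosome genome, so these counts say little about host RNA in the specimens. Infected mouse livers and human serum, which the series text mentions, were not analysed here.

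The first question was which miRNAs separate the developmental stages. In eggs, miR-36, of a family that vertebrates lack and that nematode embryos need, stood at 361335 ± 54342 (n = 3) against 22195 ± 11687 in adults (n = 10), 27.5-fold higher in the fit. The neural miRNA miR-124 reached 12344 ± 5960 against 3019 ± 1969 in adults, 6.26-fold higher. miR-8, the invertebrate counterpart of the vertebrate miR-200 family, reached 42191 ± 26588 against 13231 ± 10564, 5.70-fold higher. Both homologues of the timing miRNA lin-4 were lower in eggs, miR-125a at 4603 ± 6574 against 71045 ± 110111 and miR-125b at 26902 ± 23098 against 157215 ± 89678. miR-755 was also lower, at 680 ± 1028 against 29247 ± 57442. Single libraries carry some of these means. Without the S. mansoni unspecified adult (373673) the adult mean of miR-125a was 37419, and without the S. japonicum female that of miR-755 was 11308. In eggs the mean of miR-125a was 825 without S. mansoni egg 1, and those of miR-8 and miR-755 were 27053 and 88.9 without the S. japonicum egg.

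With species as a term, 6 of 33 tested miRNAs differed between eggs and adults, 3 higher and 3 lower, and 10 had an unadjusted p under 0.05. miR-36 rose by 4.78 ± 0.66 (SE) on the log2 scale (limma, adjusted p = 1.3e-06). miR-8 rose by 2.51 ± 0.76 (adjusted p = 0.016) and miR-124 by 2.65 ± 0.82 (adjusted p = 0.0166). miR-755 fell by 5.47 ± 1.51, miR-125a fell by 4.34 ± 1.24 and miR-125b fell by 3.30 ± 1.0, each with adjusted p = 0.016. With all reads as the library size miR-124 (2.37) and miR-8 (2.29) lost their calls, and without shallow libraries miR-124 did (2.45). All 6 showed their direction in 3 of 3 egg libraries, each set against the adult mean of its species. For miR-755 the S. japonicum egg (1863) was not below the mixed adult of that species (1835), whose adult mean rests on the female at 190693. let-7 (log2 fold change -1.85, adjusted p = 0.247), miR-31 (-1.12, 0.629), bantam (0.57, 0.727), miR-71a (0.39, 0.817) and miR-1 (-0.16, 0.881) did not pass the threshold.

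Among lists fixed in advance, 2 of 4 timing miRNAs were lower in eggs, and miR-10, near Hox genes in many animals, joined them when adjusted over the list alone, which gave 3. Of 6 muscle and neural miRNAs tested, miR-124 and miR-8 were higher, also when adjusted over the list alone. Of 12 protostome families, miR-36 was higher and miR-755 lower, with 2 adjusted over the list alone. The 7 miRNAs earlier reported in males held 1 higher (miR-124) and 2 lower (miR-125a and miR-125b), and 4 when adjusted over the list alone, with miR-61 added. None of the 7 members of the miR-71 and miR-2 clusters, the 3 miRNAs earlier reported in females or the 3 others passed the threshold. Adjusted over the list alone, each of these lists also gave 0. Over all miRNAs limma gave 10 at unadjusted p under 0.05 and 6 calls in the unweighted fit.

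Leaving out S. mansoni egg 2 left 1 of the 6 calls, that of miR-36, and added miR-3479, for a count of 2; miR-125a then stood at -2.91, miR-125b at -2.17, miR-124 at 1.42, miR-8 at 2.06 and miR-755 at -3.89. Without S. mansoni female 1 there were 3 calls, with miR-125b at -3.07, miR-124 at 2.14 and miR-8 at 2.47, and without S. mansoni cercariae there were 11, with let-7 (-2.43), miR-10, miR-133, miR-3479 and miR-61 added. miR-10, miR-61, miR-133 or miR-3479 also passed without S. mansoni egg 1, the S. japonicum mixed adult, cercariae, egg or female, the S. haematobium female or the S. mansoni male. The call of miR-124 also ended without the S. mansoni male (1.96), and that of miR-8 without S. mansoni egg 1 (2.46), the S. japonicum egg (2.36), the S. mansoni unspecified adult (2.32) or the S. mansoni male (2.03). Nearly all adult libraries carry upper-case codes and most others lower-case codes, which may mark library pools in the labels; with that code as a term only miR-36 stayed past the threshold (4.43 ± 0.76, adjusted p = 8.6e-05). The other 5 kept a median share of 0.826 of their log2 fold change, with miR-125a at -3.59 ± 1.28, miR-125b at -3.14 ± 1.15, miR-124 at 1.97 ± 0.96, miR-8 at 2.18 ± 0.87 and miR-755 at -3.47 ± 1.33.

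Cercariae, the free-swimming larvae that infect mammals, also held much miR-36, at 267810 ± 93028 (n = 3) against 22195 ± 11687 in adults, 20.4-fold higher. The neural miR-124 reached 10336 ± 5349 against 3019 ± 1969, 6.14-fold higher. The timing miRNAs miR-125b (29214 against 157215) and let-7 (7385 against 37291) were lower in 3 of 3 cercariae without passing the test. In limma, miR-36 rose by 4.35 ± 0.65 (adjusted p = 5.6e-06) and miR-124 by 2.62 ± 0.80 (adjusted p = 0.0454), both in 3 of 3 libraries, and 10 of 33 miRNAs had an unadjusted p under 0.05. miR-125b (log2 fold change -2.41 ± 0.92, adjusted p = 0.147), let-7 (-2.20 ± 1.03, 0.152), miR-1 (1.27, 0.169), miR-71a (-1.24, 0.199), miR-31 (-1.39, 0.411) and bantam (0.39, 0.785) did not pass. All 3 cercariae carry lower-case codes, and with the code as a term 1 call was left, without miR-124. With all reads as the library size 1 of 6 calls was higher, and let-7, miR-125a, miR-125b, miR-71a and miR-755 passed as lower. With 5 or 10 min DSN libraries let-7, miR-125a and miR-125b passed as lower. miR-124 lost its call under each of these settings.

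Of the lists, the 4 timing miRNAs gave 0 calls over all miRNAs tested and 2 when adjusted over the list alone (miR-125a and miR-125b), against 10 miRNAs at unadjusted p under 0.05 and 1 call in the unweighted limma fit. Muscle and neural miRNAs gave 1 of 6 (miR-124) and protostome families 1 of 12 (miR-36), each the same when adjusted over the list alone. The list earlier reported in males gave 1 of 7 (miR-124) and 2 when adjusted over the list alone, with miR-125b. In the miR-71 and miR-2 clusters 6 of 7 members had a log2 fold change above 0, and none passed. The call of miR-124 was lost when any of 13 of the 18 libraries was left out, with values from 1.37 to 2.84. It was kept only without the S. haematobium miracidia, S. mansoni miracidia, S. japonicum mixed adult, S. japonicum female or S. mansoni female 2. The count of calls was 1 without S. mansoni egg 1, the S. japonicum egg, the S. haematobium male or female, the S. japonicum male, S. mansoni female 1, or the S. mansoni unspecified or mixed adult, and 6 without S. mansoni egg 2, the S. japonicum female or the S. mansoni male, where let-7 (-2.94 to -2.81), miR-125b (-3.31 to -2.89) and miR-125a passed as lower. Calls were also added without the S. haematobium cercariae (miR-125b, -3.55), S. mansoni cercariae (miR-71a, -3.26) or S. japonicum cercariae (miR-125a and miR-87). Without the S. haematobium cercariae (61364) the mean of miR-125b in cercariae was 13140, and that of let-7 4601.

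Miracidia, the larvae that hatch from eggs, showed no common change in miR-36, with a single library per species. The S. haematobium miracidia held 50738 against 23665 and 11721 in the adults of that species, and the S. mansoni miracidia held 6489, within the 4244 to 25617 of the adults of that species. The fitted log2 fold change of miR-36 was -1.68 without the S. haematobium miracidia and 2.08 without those of S. mansoni. The muscle miRNA miR-1 stood at 210592 ± 86005, a log2 fold change of 0.79, and the timing miRNA miR-125b at a mean of 176524, a log2 fold change of 0.82. limma gave 0 calls among 33 miRNAs and 0 at unadjusted p under 0.05 (lowest adjusted p = 0.928 over all miRNAs), and the unweighted limma fit also gave 0. The other miRNAs named in every comparison were miR-36 (0.14 ± 0.97), miR-31 (-2.04), let-7 (-0.51), bantam (0.38) and miR-71a (-0.12). No list gave a call, over all miRNAs or adjusted over the list alone. A difference from eggs was not tested.

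**Figure D1:**
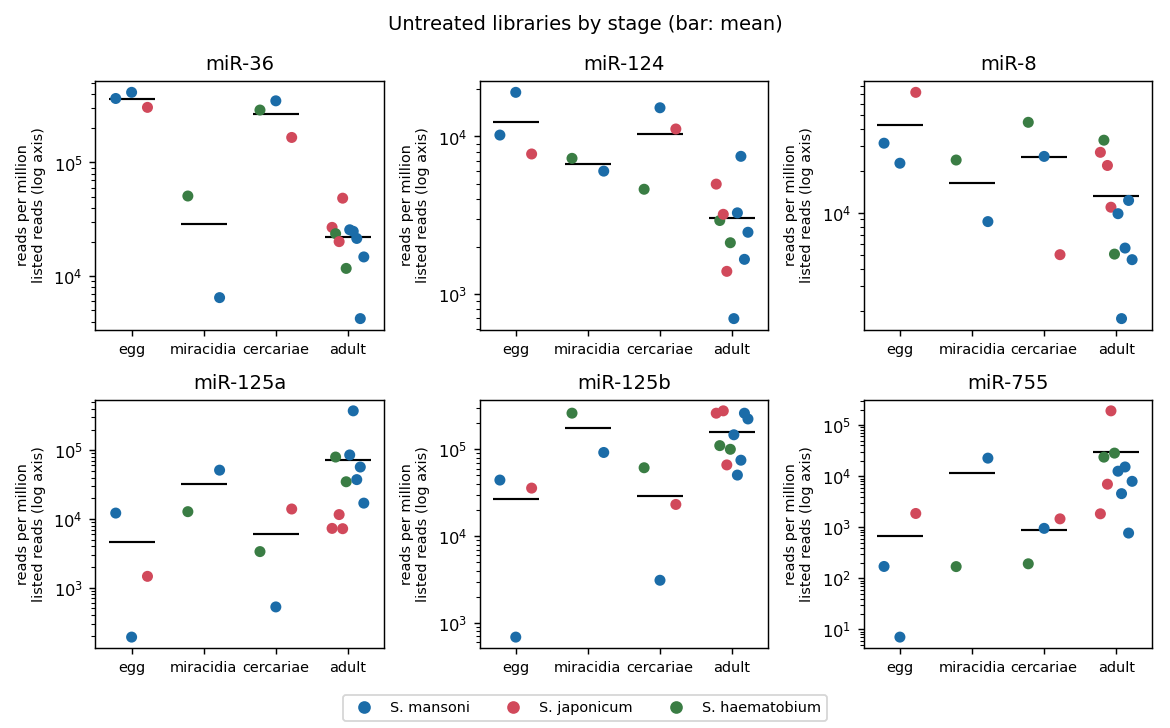
Levels of miR-36, miR-124, miR-8, miR-125a, miR-125b and miR-755 (RPM of listed miRNA reads, log axis) in the untreated libraries by stage, each point a library and each bar the mean of a stage. The mean of miR-36 is 361335 in eggs and 267810 in cercariae against 22195 in adults.

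The S. mansoni sporocyst, the stage inside the snail, and the schistosomula, the young worm after skin penetration, had 1 specimen each and were set beside the range of 9 other untreated S. mansoni libraries without a test. In the sporocyst miR-36 took 446766 RPM (Wilson 95% interval 445201 to 448332), above the 4244 to 413597 of the others. miR-124 (21119, others up to 19076) and miR-190 (44934, others up to 24693) were also above the range. miR-71a stood at 29608, under the lowest other value of 41568, and miR-7, miR-219, miR-2e, miR-1989, miR-281 and miR-745 were below their ranges too, which left 23 of the 33 miRNAs with a read in these S. mansoni libraries within. In the schistosomula miR-277b (83250, others up to 67215) was above, miR-2e (554) below and 31 within. miR-31 had 0 of 297886 listed reads there.

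The next question was how the species differ. Between S. japonicum and S. mansoni, miR-277a, of a family tied to amino acid breakdown in flies, stood at 24148 ± 2809 (n = 5) against 6.66 ± 11.4 (n = 9). Its relative miR-277b showed the opposite, 32.04 ± 20.9 against 34643 ± 17739. The low mean of miR-277a rests on few reads, with 1 read giving 34.15 RPM in S. mansoni egg 1. Most reads behind both low means carried a base change, given below, so an assembly base that differs from the RNA may account for both. miR-87 and miR-745 had 1 read each among the 4213889 listed reads of the untreated S. japonicum libraries, against levels of 10048 ± 10615 and 6750 ± 6503 in S. mansoni. miR-96 had 0 of those 4213889 reads, which by counting error alone allows up to 0.712 RPM, against 505 ± 837. Smaller differences were seen for miR-2d, of a family that represses cell-death genes in flies (13072 ± 18003 against 2329 ± 1882), and miR-190 (41193 ± 13999 against 15771 ± 5053).

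With stage as a term, limma called 7 of 33 miRNAs, 3 higher and 4 lower in S. japonicum, and 9 had an unadjusted p under 0.05. Adjusted p was 2.8e-13 for miR-277a, 1.2e-12 for miR-277b, 3.7e-12 for miR-87, 2.6e-11 for miR-745 and 4.4e-08 for miR-96, and their fitted folds are not given because they rest on counts near 0. miR-2d was higher by 2.60 ± 0.77 on the log2 scale (6.07-fold, adjusted p = 0.0105) and miR-190 by 1.51 ± 0.55 (2.84-fold, adjusted p = 0.0496). All 7 showed their direction in 5 of 5 libraries. miR-125b (1.63, adjusted p = 0.157), bantam (-1.10, 0.223), miR-1 (-0.54), miR-36 (0.46), miR-31 (-0.44), miR-71a (0.34) and let-7 (0.26) did not pass. Of the lists, 1 of 7 cluster members was called (miR-2d), 1 when adjusted over the list alone, though 7 of 7 lay above 0. Protostome families gave 1 higher and 3 lower of 12, or 4 adjusted over the list alone, and the 3 others gave 1 higher and 1 lower, or 2 adjusted over the list alone. The timing, muscle and neural, male and female lists gave 0 calls, also adjusted over the list alone, where limma gave 9 miRNAs in all at unadjusted p under 0.05 and the unweighted fit gave 6 calls. The call of miR-2d was lost without the S. japonicum mixed adult (2.14), S. mansoni cercariae (1.30), S. japonicum cercariae (1.67) or the S. mansoni male (2.01). That of miR-190 was lost without any of 16 of the 18 libraries (1.02 to 1.55) and kept only without the S. haematobium or the S. mansoni miracidia. bantam passed as lower without the S. japonicum mixed adult (-1.95) or the S. mansoni male (-1.67), miR-125a without S. mansoni cercariae or S. mansoni egg 2, and miR-8 as higher without the S. japonicum cercariae. The mean of miR-2d in S. japonicum was 5059 without its cercariae (45125), and that of miR-96 in S. mansoni 230.8 without egg 1 (2698).

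In S. haematobium, miR-190 had 0 of 446086 listed reads, which by counting error alone allows up to 6.73 RPM, against 15771 ± 5053 in S. mansoni. miR-277a was abundant, at 21791 ± 7602 (n = 4) against 6.66 ± 11.4 (n = 9). miR-2a, from the cluster led by miR-71a, had 9 reads, a level of 13.8 ± 24.4 against 11162 ± 5374. miR-96 stood at 2404 ± 1846 against 505 ± 837. limma called these 4 of 33, with adjusted p of 1.4e-12 for miR-190, 3.1e-11 for miR-277a, 9.4e-11 for miR-2a and 0.0453 for miR-96 (log2 fold change 3.04 ± 1.02, 8.21-fold), each in 4 of 4 libraries; 4 had an unadjusted p under 0.05. miR-31 (-1.68), bantam (-1.16, adjusted p = 0.638), miR-125b (1.01), miR-71a (0.86), miR-36 (0.50), let-7 (0.39) and miR-1 (0.09) did not pass. The calls fell as 1 of 7 cluster members, 1 of 12 protostome families and 2 of 3 others, each the same when adjusted over the list alone. The timing, muscle and neural, male and female lists gave 0, also adjusted over the list alone, where limma gave 4 miRNAs in all at unadjusted p under 0.05 and the unweighted fit 3 calls. The call of miR-96 was lost without any of 15 of the 18 libraries (2.57 to 3.30), and kept only without S. mansoni egg 1, the S. japonicum mixed adult or the S. japonicum female. miR-31 passed as lower without the S. haematobium female (-3.14), and the mean of miR-2a was 1.62 without the S. haematobium miracidia. With DSN libraries in place of untreated ones the log2 fold change of miR-96 was 0.47 at 5 min and 0.53 at 10 min.

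Several of the miRNAs at low levels also differed in sequence between the species, with positions counted from 1 at the 5′ end of the miRNA and the usual base first. The few S. haematobium reads of miR-2a carried A12C (10 reads over all libraries), the S. mansoni reads of miR-277a C17G (39 reads), and the S. japonicum reads of miR-277b C17A (252 reads) and of miR-745 T11C (3 reads). S. japonicum reads of miR-87 held G1T and T18G (22 reads). Elsewhere, miR-755 carried C11T (17905 reads) and miR-31 T12C (415 reads) in S. japonicum, and miR-96 T11C (785 reads) in S. haematobium. The deposited reads have no mismatch to the genome in their first 18 nt, so a read can appear only with the bases of the assembly. A locus that is missing or differs in the assembly could thus also leave a miRNA without reads. This holds for miR-190 in S. haematobium and miR-96 in S. japonicum too, so their absence from the worms was not shown. The level of miR-1 sums a pair of starts, of which TGGAATGTGGCGAAGTAT made up 98.4% in S. japonicum and TGGAATGTTGTGAAGTAT 68.0% in S. mansoni and 66.5% in S. haematobium.

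The cluster of miR-71a held the same order in the 3 genomes. miR-2a began 125 nt from miR-71a in each, miR-2b 219 nt in S. mansoni and S. haematobium and 218 nt in S. japonicum, and miR-2e 322 nt and 321 nt. Over all libraries the reads of the most abundant full-length sequence at miR-2a numbered 36260 in S. mansoni, 83517 in S. japonicum and 5 in S. haematobium. In S. mansoni the cluster lay on the plus strand of the scaffold named for the Z and W sex chromosomes, with miR-71a at 22875670 to 22875691 and miR-2a at 22875795 to 22875816; the genome build is not given in the sources used here.

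**Figure D2:**
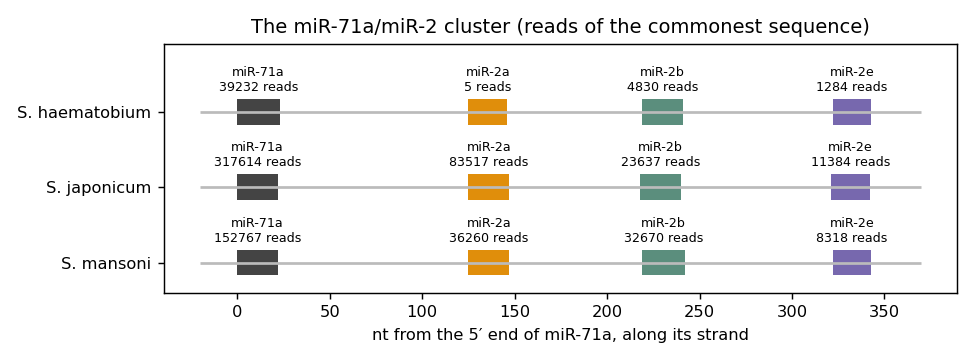
Places of miR-71a, miR-2a, miR-2b and miR-2e along the genome of each species (nt from the start of miR-71a), with the reads of the most abundant sequence at each. miR-2a lies 125 nt from miR-71a in all 3 species, with 36260 reads in S. mansoni, 83517 in S. japonicum and 5 in S. haematobium.

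The sexes of adult worms were compared next, over 4 female and 3 male libraries with species as a term. miR-1989, of a protostome family reported earlier in female schistosomes, stood at 18048 ± 9081 in females (n = 4) against 482 ± 298 in males (n = 3), 30.5-fold higher. miR-755 reached 61689 ± 86280 against 10461 ± 11827, 5.95-fold higher. miR-31, also reported earlier in females, was 10.2-fold higher at 289 ± 160 against 11.5 ± 10.3, from 3 to 323 reads per female library and 0, 1 and 12 reads in males. miR-2c was 7.72-fold higher at 299.9 ± 43.9 against 36.0 ± 31.4, from 4 to 229 reads in females and 0, 2 and 47 in males. The muscle miRNA miR-1 went the other way, at 105328 ± 62153 against 222131 ± 81677, lower in 4 of 4 female libraries, but did not pass the test. The mean of miR-755 was 18688 without the S. japonicum female and 3871 in males without that of S. haematobium, where miR-1989 stood at 319; that of miR-31 in males was 7.35 without that of S. mansoni.

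limma called 4 of 33 miRNAs, all higher in females in this fit of 7 libraries, and 9 had an unadjusted p under 0.05. miR-1989 was higher by 4.93 ± 0.90 on the log2 scale (adjusted p = 1.1e-05), miR-31 by 3.36 ± 1.02 (adjusted p = 0.024), miR-755 by 2.57 ± 0.83 (adjusted p = 0.0288) and miR-2c by 2.95 ± 1.02 (adjusted p = 0.0384), each in 4 of 4 females. miR-1 (-1.88 ± 0.72, adjusted p = 0.072), let-7 (-1.91, 0.116), miR-125b (-1.57, 0.138), bantam (1.32, 0.336), miR-36 (0.66) and miR-71a (-0.05) did not pass. bantam, which drives growth in flies, averaged 143481 in females against 33874 in males and was higher in 4 of 4. The S. mansoni male (63557) carries much of the male mean, with the S. japonicum male at 19823 and that of S. haematobium at 18241. The list reported in females gave 2 of 3 (miR-1989 and miR-31), also when adjusted over the list alone. The list reported in males gave 0 of 7, also adjusted over the list alone, with all 7 below 0 and a median of -0.92; the unweighted limma fit gave 1 call in all. Muscle and neural (0 of 6), timing (0 of 4) and other miRNAs (0 of 3) gave no call either, also adjusted over the list alone, while protostome families gave 2 of 12 and clusters 1 of 7, the same adjusted over the list alone.

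The fit had 3 residual degrees of freedom and drew its spread from all miRNAs. Both S. mansoni females were set against the same male, of strain PR1 like female 1, while female 2 was NMRI. miR-1989 kept its call without any of the 7 libraries (3.89 to 5.15). That of miR-31 was lost without the S. haematobium male (2.50), the S. haematobium female (2.49) or S. mansoni female 1 (2.901). The same fits added calls lower in females: let-7 (-2.77), miR-125b (-2.52) and miR-1 (-2.28) without the S. haematobium male, let-7 (-2.77) and miR-125b (-2.55) without the female of that species, and miR-125b (-1.87) and miR-1 (-2.05) without S. mansoni female 1. That of miR-755 was lost without the S. japonicum male (2.25), S. japonicum female (1.85), S. mansoni female 2 (2.56) or S. mansoni male (2.11), and it was 0.26 on the log2 scale in the S. haematobium pair against 4.77 in that of S. japonicum. That of miR-2c was lost without the S. haematobium male (2.98) or female (3.01), S. mansoni female 1 (2.63), S. mansoni female 2 (2.94) or the S. mansoni male (1.89). The count was 2 without S. mansoni female 2 or the S. mansoni male. In the unweighted fit, and with the 10 min DSN libraries, miR-1989 alone was called. With all reads as the library size 4 miRNAs were called, of which 1 was higher: miR-1989 kept its call, while miR-31, miR-755 and miR-2c lost theirs and let-7, miR-1 and miR-125b passed as lower.

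**Figure D3:**
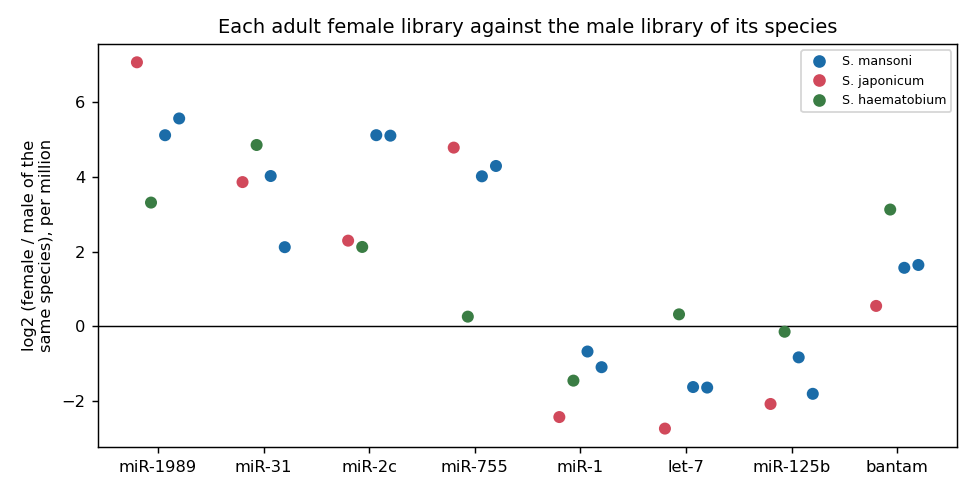
Difference between female and male (log2 of RPM of listed miRNA reads) for miR-1989, miR-31, miR-2c, miR-755, miR-1, let-7, miR-125b and bantam, each point a female library set against the male library of its species. miR-1989 lies at 7.05 in the S. japonicum pair and 3.31 in the S. haematobium pair, and miR-755 at 4.77 and 0.26.

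Female libraries differed from male ones in makeup as well, with 47.9% ± 4.16 of reads at 20 nt against 35.1% ± 4.10 and 20.7% ± 6.46 of reads in listed miRNAs against 36.3% ± 7.35 (n = 4 and 3). The 10 most abundant 18-nt starts took 18.6% ± 3.47 against 40.9% ± 11.8. Each of these differences had p = 0.0286 in a two-sided exact permutation test, the smallest that 35 splits allow, and an adjusted p of 0.0381 over 4 measures; the share at 22 nt (17.6% ± 3.95 against 26.2% ± 4.50) had an exact p of 0.0571. These splits exchange libraries across species. With exchange within species only, 12 splits exist and each of the 4 measures had the smallest exact p they allow, 0.0833, which cannot pass the threshold.

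Reads outside the list were searched for tags, the first 18 nt of a read, that differ between the sexes. The tag GAAGAAATGAGCACAACT, 60 to 73 nt from miR-1989 on its strand in the 3 genomes, was higher in females by 5.90 ± 1.52 on the log2 scale, and CGGCTTTTATTGCGCTCT, beside bantam, by 5.29 ± 1.47. Next came AGGCGCTTTGATTGTCCA (4.06 ± 1.35) and TACCTCTGGTTGACGCTG (4.25 ± 1.61), the latter at 4 to 5 genome positions, and a tag almost confined to S. haematobium (3.08). Lower in females were GAGGTAGTTAGATGTACG (-3.94 ± 0.94), AGAGGTAGTGATTCATAT (-2.54 ± 0.86), TTATTTTAGAATCGCAAC (-4.44 ± 1.59), GCCGGCGACCATACCACG (-4.21 ± 1.60) and TGTAGAATACAGATGGAC (-3.69 ± 1.53). limma called 0 of 27155 tags (lowest adjusted p = 0.723) and 46 had an unadjusted p under 0.05; the unweighted fit was not run on tags. Among the 1336 tags with at least 100 reads in at least 2 libraries it called 5, GAAGAAATGAGCACAACT (6.55), CGGCTTTTATTGCGCTCT (6.26), AGGCGCTTTGATTGTCCA (4.29), GAGGTAGTTAGATGTACG (-3.87) and AGAGGTAGTGATTCATAT (-2.54), so whether these pass depends on that limit. On simulated data of 12390 tags the test recovered 0% of 16-fold changes, so that low count says little. Without the S. haematobium male or female 5 tags were called, 3 higher and 2 lower in females. Without the shallow S. japonicum female 5 were called too, but 0 higher (limma, 594 tags in all at unadjusted p under 0.05), and the median log2 fold change of all tags went from 1.19 to -0.94. Without the S. mansoni male there were 4 (2 higher), without S. mansoni female 1 3 (2 higher) and without S. mansoni female 2 2 (2 higher).

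The last question was what DSN did to the miRNA profile. After 10 min bantam stood at 41214 against 100059 in the untreated libraries of the same 20 specimens, and miR-36 at 245331 against 135164. bantam fell by 1.17 ± 0.12 on the log2 scale and miR-36 rose by 1.26 ± 0.14, each in 20 of 20 specimens. miR-10 rose by 0.96 ± 0.10 in 18 of 20, and miR-71a fell by 0.73 in 20 of 20. The neural miR-124 fell by 0.82 in 19 of 20, miR-8 fell by 0.41 in 19 of 20, and miR-7, which acts in fly photoreceptors, fell by 0.59 in 18 of 20.

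With the specimen as a block, limma called 15 of 33 miRNAs after 10 min, 7 higher and 8 lower, and 17 had an unadjusted p under 0.05. Adjusted p was 1.0e-11 for bantam, 5.1e-11 for miR-10, 1.6e-10 for miR-36, 2.3e-06 for miR-71a, 9.6e-05 for miR-124, 0.000828 for miR-7 and 0.00102 for miR-8. miR-2a (0.78, 13 of 20), miR-277b (0.76, 16 of 20), miR-87 (0.94, 15 of 20), miR-2c (0.96, 14 of 20) and miR-3479 (0.53, 15 of 20) also rose. miR-71b (-0.45, 18 of 20), miR-755 (-0.63, 17 of 20) and miR-1989 (-0.61, 16 of 20, adjusted p = 0.0234) fell. let-7 (0.07), miR-125b (0.10), miR-1 (-0.06) and miR-31 (0.60, adjusted p = 0.109) did not pass. After 5 min 17 were called, 10 higher and 7 lower, and 18 had an unadjusted p under 0.05; bantam fell by 0.97, miR-36 rose by 1.31 and miR-10 by 1.12. Called at 5 min only were miR-219 (0.44 ± 0.18, 16 of 20, adjusted p = 0.0358), miR-281 (0.31 ± 0.10, 11 of 20, adjusted p = 0.00814) and miR-2162 (0.32 ± 0.10, 8 of 20, adjusted p = 0.00771). The counts of specimens are of RPM, by which most specimens did not show the rise of miR-2162. The fit gave the same spread to all libraries of a specimen, although those of 5 and 10 min were much alike. It may thus understate the error of either against untreated, so these adjusted p-values can be too low. Between 10 and 5 min limma called 0 miRNAs (lowest adjusted p = 0.916, 0 at unadjusted p under 0.05; no other tool was run), and the median size of the change was 0.11 against 0.40 between 5 min and untreated.

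By list, after 10 min 3 of 6 muscle and neural miRNAs were lower, 2 of 3 reported in females lower, 2 of 7 reported in males lower and 1 of 4 timing miRNAs higher, each the same adjusted over the list alone. Clusters gave 2 higher and 2 lower of 7 (4 adjusted over the list alone), protostome families 3 higher and 3 lower of 12 (6) and others 1 higher of 3 (1). Directions are relative to the scaled listed total. With all reads as the library size 2 of 20 calls were higher after 10 min and 2 of 21 after 5 min. With median-of-ratios scaling these were 13 of 18 and 15 of 20. Without the specimen as a block both counts were 0, with 3 miRNAs at unadjusted p under 0.05 after 5 min and 4 after 10 min. On simulated data the blocked fit called 7.12% of unchanged miRNAs where 8 of 33 changed 2-fold. At 5 min the call of miR-219 was lost without any of 17 of the 20 specimens (0.16 to 0.43), and kept only without the S. mansoni sporocyst, S. haematobium miracidia or S. japonicum male. Those of miR-281 (0.04 to 0.25) and miR-2162 (-0.01 to 0.30) were lost without any of 13, and kept without the S. haematobium miracidia, S. mansoni egg 1, the S. japonicum cercariae, egg or male, or the S. mansoni unspecified or mixed adult. At 10 min that of miR-1989 was lost without the S. haematobium cercariae (-0.58) or male (-0.54), the S. japonicum mixed adult (-0.61) or cercariae (-0.44), S. mansoni miracidia (-0.57), S. mansoni female 2 (-0.50) or the S. mansoni male (-0.48). That of miR-755 was lost without the S. haematobium male (-0.40), S. mansoni female 2 (-0.37) or the S. mansoni male (-0.45), that of miR-7 without the S. mansoni male (-0.44), and that of miR-3479 without S. mansoni female 1 (0.34). miR-1 passed as lower at 10 min (-0.25 to -0.23) without the S. mansoni schistosomula, sporocyst, cercariae, egg 2 or female 1, the S. japonicum female or the S. haematobium female. At 5 min (-0.32 to -0.27) it passed without any of these, the S. japonicum mixed adult or S. mansoni miracidia.

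**Figure D4:**
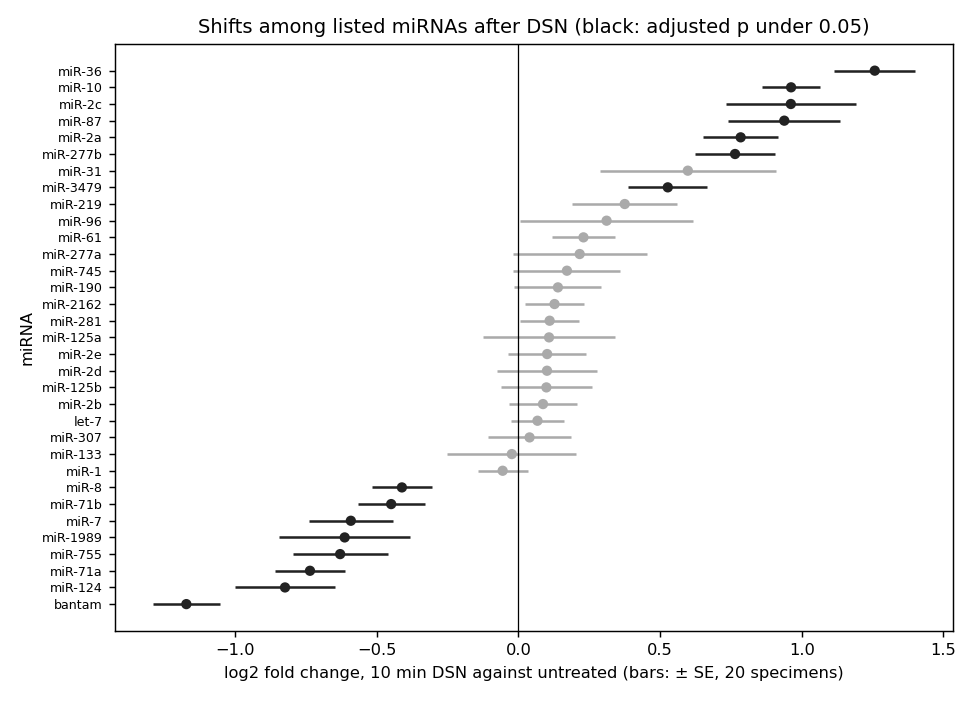
Log2 fold change of each tested miRNA after 10 min of DSN against untreated (point, with the SE as a bar, 20 specimens), black where called. bantam lies lowest at -1.17 and miR-36 highest at 1.26.

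Listed miRNAs took 32.4% ± 11.6 of reads in untreated libraries and 25.8% ± 11.8 after 10 min, a difference of -6.59 ± 9.51 percentage points (n = 20, lower in 16 of 20, two-sided paired permutation p = 0.00119). The 10 most abundant starts took 37.5% ± 15.5 and 33.8% ± 16.9, a difference of -3.74 ± 7.92 (lower in 16 of 20, permutation p = 0.0433), which no longer passed the threshold when any of 12 of the 20 specimens was left out (-3.77 to -2.66). It passed without the S. haematobium miracidia, cercariae or male, or the S. mansoni sporocyst, cercariae, egg 1, egg 2 or mixed adult. For the 100 most abundant starts the difference was -6.69 ± 8.08 (lower in 17 of 20, permutation p = 0.00075). Other measures moved too, without a test: the mapped share, an upper bound, had a mean of 27.6% untreated and 12.96% after 10 min, the share of reads at 22 nt 24.1% and 16.8%, and mapped reads a median of 470913.5 and 90713.5. Untreated libraries list another 3′ adapter set than DSN libraries in the labels, so DSN and adapter cannot be told apart.

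**Figure D5:**
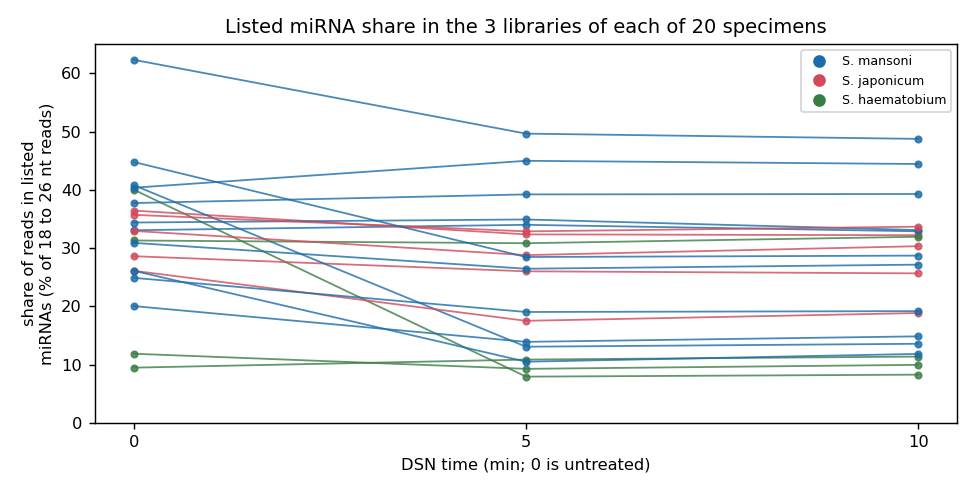
Share of reads in listed miRNAs (percent) in the untreated, 5 min and 10 min libraries, each line a specimen. The mean is 32.4% untreated and 25.8% after 10 min, and the share is lower after 10 min in 16 of 20 specimens.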

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

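Of the tests in this part, that of GC content was written before its result was seen, and the others were chosen only after the result was seen. The search for libraries far from the rest covered 76 groups of 4 to 10 libraries and found 6; chance alone marks about 1 in 20 groups, so some of these are probably chance. No called effect among 12 checked went opposite ways in the species.

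The S. japonicum female library, 1 of the shallowest, lay far below the others 3 times. Its miR-1 stood at 14.55 (log2 RPM) against 16.50 to 18.06 in 9 other adults, a gap of 0.557 of the whole range. Its bantam stood at 14.82 against 17.28 to 17.60 in the other females (gap 0.884), and its let-7 at 12.16 against 14.49 to 14.87 (gap 0.858). In S. mansoni, miR-190 was lowest in the unspecified adult, at 12.60 against 13.69 to 14.59 (gap 0.549), and miR-96 highest in egg 1, at 11.41 against 6.44 to 8.88 (gap 0.508). In S. japonicum, miR-71a was lowest in cercariae, at 13.30 against 17.04 to 17.79 (gap 0.832). The last signal came from reads that no comparison used: reads near the synthetic spike-in sequences made up 714.1 RPM of reads of 18 to 26 nt in the 12 S. haematobium libraries (2971 reads) against 1.99 in the other 48 (71 reads). Larvae carry that value, with 2014 to 3351 RPM in the S. haematobium cercariae and 1784 to 1949 in the miracidia. The adults of that species held 22.9 to 92.3, from 1 to 62 reads per library. The untreated S. mansoni mixed adult held 357, from only 5 reads. The 714.1 RPM became 403 without the untreated S. haematobium cercariae and 1199 without the untreated S. haematobium female.

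miR-2a was nearly missing in S. haematobium and miR-277a in S. mansoni. Loss of the gene is argued against by reads at the usual places, 125 nt from miR-71a and 266 nt from miR-277b (275 nt in S. haematobium). An assembly base that differs from the RNA read may explain both, since a mapped read must match the assembly over its first 18 nt: the reads with A12C and C17G numbered 0.732 and 0.491 times what sequencing errors at those bases would give, with error rates taken from nt 19 and 20 as an approximation. A low true level stays open, since the reads differed from the error estimate by -3.66 for miR-2a and -40.4 for miR-277a, and the estimate is rough. The biological alternative, a species difference in sequence or level, stays untested without the unmapped reads. No such estimate was made for the S. japonicum reads of miR-277b (C17A), miR-745 (T11C) or miR-87 (G1T and T18G), where an assembly base stays open too. The assembly stays open also for miR-190 in S. haematobium and miR-96 in S. japonicum.

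bantam, miR-71a and miR-124 fell and miR-36 and miR-10 rose after the nuclease. If the enzyme took most from abundant cDNA, the log2 fold change would fall with the untreated level: Pearson r was -0.263 (permutation p = 0.140; Spearman rho -0.236, permutation p = 0.187; r -0.269 without the 2 farthest) across 33 miRNAs, which are not independent replicates, and this leaves it open. GC content gave r 0.231 (permutation p = 0.196; rho 0.105, permutation p = 0.557; r 0.106 without the 2 farthest), also open, with adjusted p = 0.196 for both of these 2 relations. The other 3′ adapters of untreated libraries could act in the same way, and limma found 0 calls between 10 and 5 min, 0 at unadjusted p under 0.05, which either cause allows. No biological explanation was tested, since the libraries share their specimens.

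Eggs and adults differ in library code as well as stage, apart from the S. japonicum egg and mixed adult. For miR-36 the pool as the whole cause is argued against, since its log2 fold change went from 4.78 ± 0.66 to 4.43 ± 0.76 with the code as a term. For miR-125a (-4.34 ± 1.24 to -3.59 ± 1.28), miR-125b (-3.30 ± 1.0 to -3.14 ± 1.15), miR-124 (2.65 ± 0.82 to 1.97 ± 0.96), miR-8 (2.51 ± 0.76 to 2.18 ± 0.87) and miR-755 (-5.47 ± 1.51 to -3.47 ± 1.33) the calls ended because the estimates shrank and most errors grew. A median share of 0.826 of the change remained, more than the pool as the main cause would leave, but none of the 5 passed and only the S. japonicum egg and mixed adult separate code from stage, which keeps a part of the pool open. The stage itself stays a possible cause of all 6.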

How the results depend on the processing

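The alternatives chosen only after the data were seen were median-of-ratios scaling, the unweighted limma trend fit, miRNAs not found in a species set missing, shallow libraries left out, and shorter reads and exact matching for the sporocyst and schistosomula. The fit with DESeq2 size factors and its own test was not run. A named tag that was not tested under a setting has no value there. For the sum per comparison, counts of calls were compared by size alone, whichever miRNAs were called and in whichever direction. Shares were compared by direction and side of the threshold. Under other settings 84 of these sums stayed similar, 17 became weaker and 7 stronger. For single miRNAs 940 kept their direction and side of the threshold, 106 became weaker, 33 stronger and 56 reversed. With 1 library or specimen left out 150 sums stayed similar, 24 became weaker and 10 stronger. Single miRNAs then gave 1557 kept, 133 weaker, 56 stronger and 106 reversed. Most reversed values belong to miRNAs that did not pass the test. Where values below moved, the cause was not tested.

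With all reads as the library size, the calls for cercariae went from 2 to 6, with bantam at -0.35; miR-124 lost its call (1.69) and let-7, miR-125a, miR-125b, miR-71a and miR-755 gained one. For eggs miR-124 (2.37) and miR-8 (2.29) lost theirs. The median log2 fold change of all miRNAs moved from 0.27 to -0.49 for cercariae, 0.28 to 0.05 for eggs, 0.35 to 1.06 for miracidia, 0.03 to -0.84 for S. haematobium, -0.15 to -0.62 for females, 0.21 to -0.40 after 5 min and 0.11 to -0.40 after 10 min of nuclease, and directions shift with it. For miracidia let-7 came to 0.14 and miR-71a to 0.53. For S. haematobium let-7 came to -0.44, miR-1 to -0.92 and miR-36 to -0.51. After 5 min let-7 came to -0.46, miR-125b to -0.39, miR-219 to -0.19, miR-31 to -0.045, miR-281 to -0.28 and miR-2162 to -0.32; after 10 min let-7 came to -0.46 and miR-125b to -0.43. Of the calls with the nuclease, 11 at 5 min and 10 at 10 min were also called under this setting, whatever their direction. miR-219, miR-281 and miR-2162, above 0 in the main fit at 5 min, were below 0 here. The calls split into 1 higher of 6 for cercariae (2 of 2 before), 1 of 4 for eggs (3 of 6) and 1 of 4 for females (4 of 4).

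Median-of-ratios scaling gave 1 call for cercariae, miR-36 at -0.10 for miracidia, let-7 at -0.0086 and miR-71a at -0.0029 for S. japonicum, and miR-1 at -0.32 for S. haematobium. It put miR-71a at 0.39 for females, and miR-1 at 0.077 after 5 min and 0.12 after 10 min. Its medians were -0.01 for cercariae, -0.11 for eggs, 0.20 for miracidia, 0.06 for S. japonicum, -0.34 for S. haematobium, 0.31 for females, 0.32 after 5 min and 0.27 after 10 min. Calls split into 3 higher of 8 for eggs, 2 of 6 for S. japonicum and 1 of 3 for S. haematobium (3 of 7 and 2 of 4 before).

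Reads of 20 to 24 nt gave 1 call for cercariae, miR-36 at -0.20 for miracidia, let-7 at -0.15, miR-71a at -0.10 and miR-36 at -0.013 for S. japonicum, miR-1 at -0.18 for S. haematobium, and a change in the share of the 10 most abundant tags of -2.37, which did not pass (permutation p = 0.228). The unweighted limma fit gave 1 call each for cercariae and females. Exact matching put miR-1 at 0.24 for S. japonicum, and summing the libraries of a specimen put miR-71a at 0.084 for females. With the pool as a term cercariae had 1 call and eggs 1, and miR-36 came to -0.58 for miracidia.

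Without shallow libraries cercariae had 1 call and eggs 5, without miR-124 (2.45 for eggs). let-7 came to 0.42 and bantam to -0.015 for miracidia, miR-1 to -0.27 and miR-36 to -0.12 for S. haematobium, 5 unlisted tags were called, all lower in females, and the share of the 10 most abundant tags changed by -3.54, which did not pass (permutation p = 0.0838). With miRNAs not found in a species set missing there, 1 call was left for S. japonicum and 0 for S. haematobium (limma, 1 at unadjusted p under 0.05), where miR-277a came to -0.40; this setting removes the miRNAs near 0 from the test by construction. With tags treated so, 10 tags of 270 were called, 3 higher and 7 lower in females, and with at least 100 reads in at least 2 libraries 5 of 1336, all 5 among the named tags.

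With the 5 min libraries in place of the untreated ones cercariae had 4 calls, with bantam at -0.74, and eggs 10. The call of miR-124 for cercariae was lost (1.48) and let-7, miR-125a and miR-125b gained one. For miracidia miR-125b came to -0.28 and bantam to -0.20, for S. japonicum miR-71a to -0.065, for S. haematobium let-7 to -0.17, miR-1 to -0.48 and miR-36 to -0.54, and for females miR-71a to 0.53. With the 10 min libraries cercariae had the same 4 calls, without miR-124 (1.52) and with bantam at -0.85, and females 1, with miR-71a at 0.71. bantam came to -0.032 for eggs. For miracidia miR-125b came to -0.30, bantam to -0.37 and miR-31 to 0.66. For S. japonicum let-7 came to -0.053, miR-71a to -0.28 and miR-36 to -0.15, and for S. haematobium let-7 to -0.16, miR-1 to -0.40 and miR-36 to -0.61. With 5 in place of 10 min the share of the 10 most abundant tags changed by -3.66, which did not pass (permutation p = 0.0599), and with the 100 most abundant tags the change was -6.69 (permutation p = 0.00075).

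Some calls ended under most settings. That of miR-124 for cercariae also ended with reads of 20 to 24 nt (2.44), median-of-ratios scaling (2.33), the unweighted fit (2.59), shallow libraries left out (2.53) and the pool as a term (1.55). That of miR-190 for S. japonicum ended under every other setting (1.04 to 1.61) except the fit without a filter on low counts, and that of miR-2d with the 10 min libraries (1.86). That of miR-96 for S. haematobium ended under every other setting (0.47 to 3.12) except that fit and shallow libraries left out. For females miR-31 lost its call with the 5 min libraries (1.94), miR-2c with reads of 20 to 24 nt (2.9005) and miR-755 without shallow libraries (1.85).

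Without the replicate block, that is without pairing libraries by specimen, limma called 0 miRNAs after 5 min (3 at unadjusted p under 0.05) and 0 after 10 min (4), because the spread between specimens then enters the error. miR-755 came to 0.0093 after 5 min and miR-125b to -0.036 after 10 min. The changes in the listed share (-6.59) and in the share of the 10 most abundant tags (-3.74) kept their size but did not pass unpaired.

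Leaving out each library gave 1 to 6 calls for cercariae, with miR-71a from -3.26 to 0.11 and bantam from -0.53 to 0.58. For eggs it gave 2 to 11 calls, miR-1 from -0.80 to 0.21, miR-71a from -0.71 to 0.72 and bantam from -0.11 to 0.77. For miracidia let-7 ranged from -1.33 to 0.47, miR-125b from -0.018 to 1.47, miR-1 from -0.19 to 1.63, miR-71a from -0.61 to 0.25, bantam from -0.33 to 0.81 and miR-36 from -1.68 to 2.08; 1 library then stands for the stage and is assumed to vary like the others. For S. japonicum let-7 ranged from -0.59 to 0.61, miR-71a from -0.41 to 0.93, miR-31 from -1.11 to 0.31 and miR-36 from -0.28 to 0.62. For S. haematobium let-7 ranged from -0.36 to 0.65, miR-1 from -0.36 to 0.20 and miR-36 from -0.11 to 0.72. For females there were 2 to 5 calls, miR-71a from -0.65 to 0.17 and miR-36 from -0.15 to 0.84, and 0 to 5 unlisted tags were called.

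Leaving out each specimen put let-7 from -0.14 to 0.21, miR-125b from -0.019 to 0.34 and miR-2162 from -0.0063 to 0.33 after 5 min, and let-7 from -0.16 to 0.15, miR-125b from -0.091 to 0.23 and miR-1 from -0.25 to 0.035 after 10 min. The share of the 10 most abundant tags changed by -4.54 to -2.66. Depth limits the comparison of the sexes for miR-31 and miR-2c, among others, since male libraries held 0 to 47 reads of them. The number of sporocyst and schistosomula values outside the range of other libraries was 12, and 11 with reads of 20 to 24 nt.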

Other observations

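The tests in this part, splits of the samples included, were all chosen only after the result was seen. The second cluster with members of the miR-2 family, led by miR-71b, kept its order as well. miR-2c began 173 nt from miR-71b in S. mansoni, 171 nt in S. haematobium and 168 nt in S. japonicum, and miR-2d 284, 282 and 279 nt. miR-277a and miR-277b lay 275 nt apart in S. haematobium and 266 nt in S. mansoni, and on different scaffolds in the S. japonicum assembly. In S. mansoni miR-36 had 2 positions on the minus strand of chromosome 1, at 57476978 to 57477000 and 57514921 to 57514943, so its reads cannot be split between them. miR-1989 lay at 285610 to 285631 on the minus strand of scaffold SC_0170, which also holds the tag GAAGAAATGAGCACAACT at 285550 to 285571.

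That tag and CGGCTTTTATTGCGCTCT, 2 of the named tags higher in females without passing the test over all tags, may be the other arms of the precursors of miR-1989 and bantam. The first lay 60, 73 and 60 nt from miR-1989 and the second -37, -53 and -38 nt from bantam, on the same strand in all 3 species. Of 4222 unlisted tags with at least 100 reads, 18 (0.426%) lay within 100 nt of a listed miRNA on its strand. The places thus fit precursor arms better than chance nearness, but no folding of the precursors was tested.

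Other splits of the same libraries were refitted for each count of calls. Since species and stage are terms of the fits, splits were also made that exchange libraries only within a species (stages and sexes) or within a stage (species). For eggs few splits reached the real count (6 calls, highest other 2, with 1 of 100 free splits and 1 of 84 within species reaching 6, the real split included). Few did so for S. japonicum (7 calls, highest other 3 and 7, with 1 of 100 and 2 of 100) and S. haematobium (4 calls, highest other 4 and 3, with 2 of 100 and 1 of 84). In both of these species another split reached the real count. Few splits also reached the counts for nuclease for 5 min (17 against 6, 1 of 100) and 10 min (15 against 7, 1 of 100), exchanged within specimens. These shares were not adjusted over the comparisons, so they make chance less likely but do not exclude it. For cercariae chance stays open: the 2 calls were reached by 3 of 100 free splits but by 4 of 72 within species, with 4 as the highest other count in each. For females 1 of 34 free splits reached the 4 calls (highest other 3), but within species only 12 splits exist (highest other 2), too few for a share under 0.05. For unlisted tags the splits decide nothing, since the real count was 0 (limma, 46 tags at unadjusted p under 0.05) and all 34 of 34 splits reach that by construction. Another split called 26472 tags, for a reason that was not tested, so counts from the tag fit are unsteady. With 0 reads in both sexes, miR-9 came to 5.69 on the log2 scale in the S. japonicum pair. It came to -2.38 in the S. haematobium pair and to -3.74 and -3.61 in those of S. mansoni. Values of tags near 0 thus rest on the prior count and the depth.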
